A study of Mus musculus with 2 samples.

How the data were processed

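Total RNA from the left cerebral cortex, female adult tissue of the mouse strain 5xFAD/CAST at 8 to 10 months, was profiled in 2 libraries, which the labels number as biological replicates 1 and 2 of 1 group. Mice of the 5xFAD line carry human transgenes with mutations of familial Alzheimer disease under a Thy1 promoter, and CAST is a wild-derived inbred strain. The labels give the strain and no genotype. Both libraries cite the same donor record and separate biosample records, and nothing says that they came from separate animals, so the spread between them may be technical. Per the labels, each library was made from 300 ng of RNA with spike-in RNA and a stranded, ribosome-reduced protocol. No control or other group was analysed here, so the text gives levels with their spread and describes how the 2 libraries differ. The difference between 2 single libraries has no replicate check, and no p-value across genes is given.

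Each library had a gene table and 2 transcript tables. Per the notes deposited with the files, they refer to the mouse genome build mm10 and GENCODE annotation M21, and gene names, types and coordinates were taken from that annotation. The gene table and the first transcript table hold expected counts, TPM and FPKM, as deposited by the authors from an alignment to the transcriptome. The deposited isoform percent gives each transcript's share of its gene's TPM. The deposited bounds of the TPM interval were read and not used in a comparison. The second transcript table holds estimated counts and TPM, deposited by the authors from reads and an index without that alignment. The aligner, the quantifiers and their versions are not given in the sources used here. Reads of CAST alleles that differ from the reference could be assigned less well in both libraries. Human transgene sequences are not part of the mouse annotation and were not analysed here.

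Expected counts were rounded to whole numbers. Genes summed to 28150272 counts in replicate 1 and 28065958 in replicate 2, over 55536 annotated genes. Entries for spike-in RNA, phiX and tRNA stayed out of library sizes. Spike-ins held 0.479% of all counts in replicate 1 (exact binomial 95% interval 0.477% to 0.482%) and 0.421% in replicate 2 (0.418% to 0.423%). The 26248 tRNA entries held 5 and 6.87 counts. A count of 0 allows up to 0.107 CPM in either library, taking 3 counts as the limit. Intervals and limits cover counting error only.

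Libraries were scaled with TMM in edgeR 4.0.16 (R 4.3.3), over genes with a mean of at least 10 counts. The common biological coefficient of variation came from edgeR with an intercept-only design. Log2 ratios are replicate 2 minus replicate 1, on scaled counts with a pseudocount of 0.5. A gene counted as over 2-fold apart when its scaled ratio exceeded 2 in either direction and its mean was at least 100 counts. Each ratio has an exact binomial 95% interval. The 34 gene lists covered cell types, neighbouring brain regions and pathways. Each list's median log2 ratio was set against 10000 random lists of the same size matched on mean expression, and a list was called apart outside the central 95%. Members needed a mean of 10 counts, and a list needed 5 such members. List levels are medians over members of the mean TPM. Correlations across genes used log2(TPM + 1), and genes are not independent replicates. The 2 libraries were compared by a chi-square test for duplicates. The share of a gene's 50-mers that also occur in another gene's transcripts was computed from the annotated transcripts, and over 50% was taken as shared sequence. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

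The 34 lists, the comparisons of the report with their thresholds, and the alternatives were fixed before the data were examined, except for 2 alternatives that leave out genes with shared sequence. The tests of explanations, with their 15 further choroid plexus genes and 10 microglial genes, were added later. The text names the 3 members of each list with the highest mean TPM and the 1 with the largest log2 ratio. It also names all members of the lists for plaque-associated microglia, APP processing and sex, the 10 protein-coding and 5 other genes with the highest TPM, and the 10 largest ratios each way. Isoform shares were fixed for 10 genes. Some genes that these rules name are not reported here, though they count in their lists. Ctgf was looked up as Ccn2, its name in the annotation, and where a symbol had several entries the one with the most counts was used.

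The scripts were tested on simulated data for replicate 2 against replicate 1, with 55536 genes and 200 of them changed by a log2 ratio of 2 up or down. Of these, 93.5% were called, and 1 unchanged gene was called. The 13 missed genes fell under the count minimum. A simulated coefficient of variation of 0.1 came back as 0.099 without changed genes and as 0.15 with them, so a few very different genes raise this estimate. With the changed genes present, a list shift of -0.3 came back as -0.21, and 3 of 32 unshifted lists were called apart. This was 1 draw, which cannot tell an effect of the changed genes on the lists from random spread. A further 20 repeats had no other gene changed and used library totals and fewer random lists. There the shift came back as -0.287 ± 0.056 (SD over repeats), and 4.84% of unshifted lists were called apart. Simulated genes varied independently of each other. Alternatives covered DESeq2 1.42.0 size factors and dispersion, library totals, spike-in totals, count filters, deposited TPM and FPKM, the second transcript table, pseudocounts and each replicate alone.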

Results

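Total RNA of the left cerebral cortex was measured in 2 libraries of female mouse tissue labelled 5xFAD/CAST, after an Alzheimer disease model line and a wild-derived strain. Both libraries had similar depth, with 28150272 counts on genes in replicate 1 and 28065958 in replicate 2. Transcripts were detected at 1 TPM or more for 13366 nuclear protein-coding genes in replicate 1 and 13419 in replicate 2. The labels name no second group, so the questions here are which genes the tissue expressed and how far the 2 libraries differed. Levels are given as mean TPM ± SD with n = 2 throughout, and coordinates refer to mm10.

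Protein-coding genes of the nucleus took 78.9% ± 0.558 of gene counts and 44.4% ± 0.59 of TPM. Short structural RNAs took much of the rest on the TPM scale. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, were each at 129800 ± 1573 TPM, and Rn7sk, which restrains transcription elongation, was at 69710 ± 1837 TPM. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 followed at 46120 ± 1984 and 37590 ± 1291 TPM. The 10 protein-coding genes with the highest TPM were mt-Co1 (6778 ± 265), mt-Co3 (4542 ± 175), mt-Cytb (3870 ± 158), mt-Nd1, mt-Atp6, mt-Nd4l, mt-Atp8, mt-Nd4, mt-Nd2 and Thy1 (1788 ± 66.7). Of nuclear genes, Thy1 ranked first, with TPM summed over its transcripts. Its coding transcript Thy1-201 was at 853 ± 11.8 TPM and the short non-coding Thy1-203 at 917 ± 56.1 TPM. The rank is therefore that of the gene and not of its coding transcript. Thy1-203 lies within the last exon of Thy1-201, so the levels of these transcripts depend on how shared reads were divided. Cst3, Fth1, Apoe, Eef1a1, Snap25, Actb, Gapdh, Aldoa and Snurf came next, between 1499 ± 141 TPM for Cst3 and 1038 ± 26.1 TPM for Snurf. Rn7s1 and Rn7s2 had equal counts in each library and share 100% of their 50-mers. Several ranks of protein-coding genes rest on the gene table. In the second transcript table mt-Atp8 was at 0.704 and 1.89 TPM. Snurf, which shares 100% of its 50-mers, was at 0 there in both libraries. There mt-Atp6 (3321 ± 933 TPM in the gene table) was at 5841 and 5795 TPM, above mt-Co3 at 3026 and 3904. These 2 genes share 99.5% and 99.9% of their 50-mers with other genes. Eef1a1 was at 1675 and 1695 TPM there, against 1685 and 1538 for Cst3. Xist, the RNA of the inactive X chromosome, was at 73.1 ± 2.54 TPM. Of the Y-linked genes, Ddx3y and Eif2s3y had 0 counts in both libraries, Uty had 1 count in each, and Kdm5d had 2 counts in replicate 1 and 0 in replicate 2. In the second transcript table Uty was at 1.00 and 1.80 TPM and Kdm5d at 0.645 and 0.696 TPM. Ddx3y was at 0.096 and 0.030 TPM there and Eif2s3y at 0.013 and 0.014 TPM.

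Genes known from microglia around amyloid plaques were expressed in both libraries. Apoe, a lipid carrier of astrocytes and activated microglia on chromosome 7 (19696109 to 19699188), was at 1311 ± 137 TPM. The lysosomal proteases Ctsd and Ctsb were at 564 ± 64.7 and 296 ± 15.4 TPM. Tyrobp and Trem2, the adaptor and receptor of a lipid-sensing pathway of microglia, were at 159 ± 21.8 and 54.0 ± 6.36 TPM. Cst7, a cystatin induced in plaque-associated cells, was at 46.9 ± 6.31 TPM. Itgax was at 9.70 ± 0.255 TPM and Clec7a at 6.74 ± 0.955 TPM. Ctsl, Ctsz, Ank, Lyz2, Cd63, Cd9, Cd68, Axl, Lpl, Csf1, Cd52 and Gpnmb ranged from 87.9 ± 5.07 TPM for Ctsl to 13.04 ± 2.89 TPM for Gpnmb, and the chemokine gene Ccl6 was at 12.02 ± 2.36 TPM. Spp1 was at 8.74 ± 1.21 TPM, and Lgals3 was near the detection limit at 0.77 ± 0.0283 TPM. In all, 22 of the 23 members reached 1 TPM in both libraries, and the list had a median of 46.9 TPM. No cortex labelled non-transgenic was analysed here, and the labels give no genotype, so these levels are not a measure of induction.

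Genes of the substrate and enzymes of amyloid formation were expressed in both libraries. App on chromosome 16 (84949685 to 85173766) was at 579 ± 15.9 TPM, against 912 and 920.0 TPM in the second transcript table. Its relatives Aplp1 and Aplp2 were at 526 ± 10.2 and 246 ± 7.62 TPM. The beta-secretase Bace1 was at 30.5 ± 3.55 TPM, against 3.69 ± 0.255 TPM for Bace2. Of the gamma-secretase genes, Psenen, Aph1a and Ncstn were at 45.2 ± 2.43, 32.1 ± 1.23 and 28.3 ± 2.52 TPM. Psen2 was at 8.93 ± 0.354 TPM and Aph1b at 8.36 ± 0.262 TPM. The alpha-secretase genes Adam10 and Adam17 were at 29.2 ± 0.0212 and 8.07 ± 1.85 TPM. The amyloid-degrading peptidases Ide and Mme were at 16.0 ± 1.98 and 4.73 ± 0.856 TPM. The list had a median log2 ratio of -0.02, within the central 95% of random lists, but was outside it in the second transcript table at -0.036. Values for App are those assigned to the mouse gene as annotated, and whether reads of human transgenes add to them was not tested.

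**Figure D1:**
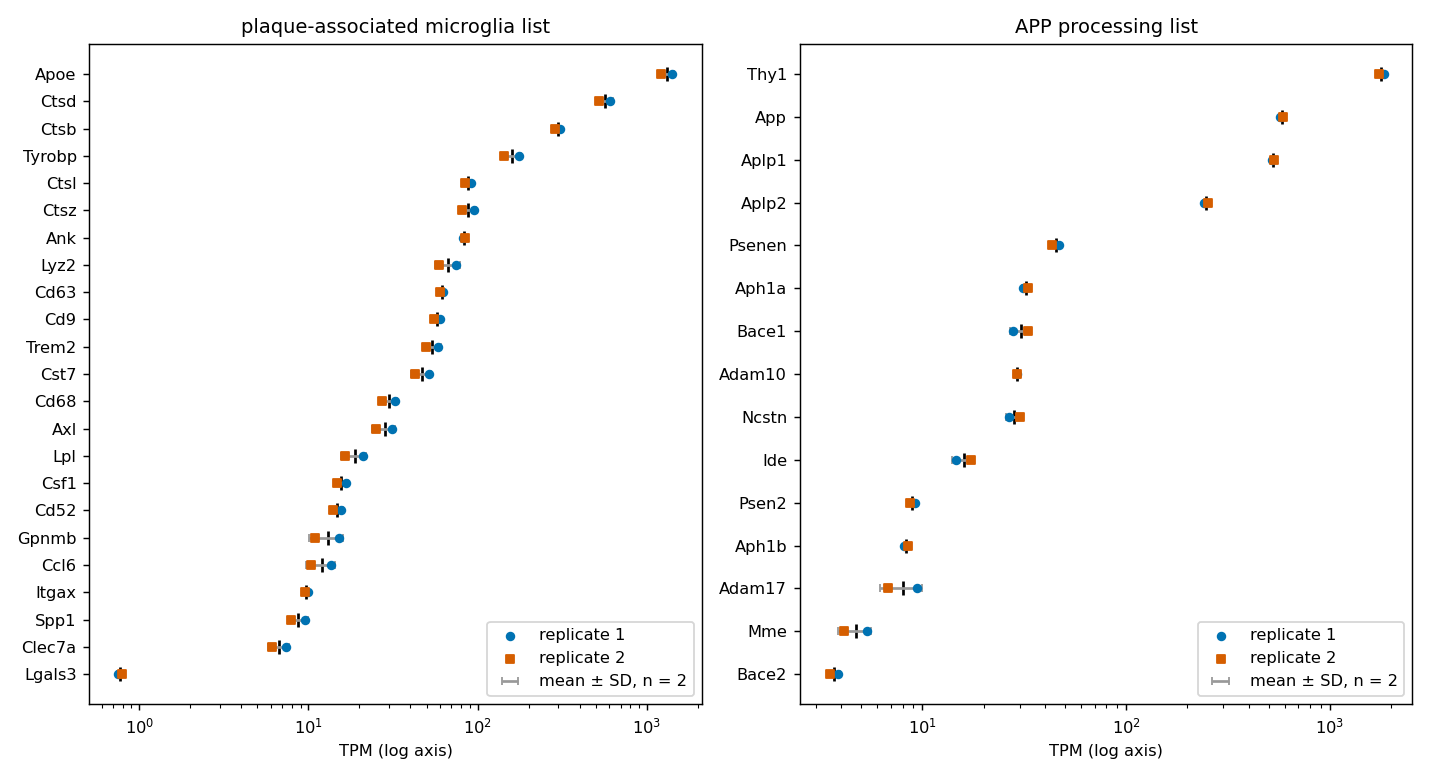
TPM on a log axis for the members reported of the plaque-associated microglia and APP processing lists, with replicate 1 as circles, replicate 2 as squares and bars for mean ± SD (n = 2). Of the plaque-associated genes, 22 of 23 had a log2 ratio of scaled counts under 0, that is, lower in replicate 2.

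Marker genes of neurons, glia and vessels were expressed in both libraries. Of the 34 lists, 21 had a median of at least 10 TPM. Snap25 (1225 ± 16.5), Syp (745 ± 29.1) and Vamp2 (438 ± 14.6) led the synapse list, whose median was 182 TPM. Camk2a (990 ± 46.1), Nrgn (685 ± 0.396) and Slc17a7 (426 ± 6.5) led excitatory neurons. Gad1 (175 ± 0.537) and Sst (157 ± 8.78) led inhibitory neurons. Rasgrf2, Cux2 and Wfs1 marked upper layers at 69.1 ± 4.94, 60.6 ± 5.63 and 59.4 ± 2.57 TPM, and Bcl11b, Etv1 and Hs3st4 deep layers at 35.6 ± 0.424, 22.5 ± 2.84 and 21.9 ± 0.205 TPM. Slc1a2 (691 ± 50.4), Aldoc and Slc1a3 led astrocytes. Mbp (713 ± 49.2) and Mobp were among the most abundant oligodendrocyte genes, and Ptprz1, Olig1 and Pdgfra led their precursors. Ly6c1, Slco1a4 and Flt1 led endothelial cells, and Vtn, Rgs5 and Acta2 mural cells. Of reactive astrocyte genes, Gfap was at 448 ± 73.6 TPM, C4b at 92.6 ± 16.6 and Serpina3n at 46.8 ± 10.8. Striatal genes were present in both libraries, with Ppp1r1b at 226 ± 14.6, Penk at 155 ± 1.63 and Pde10a at 82.4 ± 10.8 TPM.

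Across 27930 genes above 0 in either library, log2(TPM + 1) had a Pearson r of 0.989 and a Spearman rho of 0.951. The common biological coefficient of variation was 6.29% over 18599 genes, and it was higher by DESeq2 dispersion, as given in the last section. The chi-square statistic was 4.89 times its degrees of freedom, so the libraries differed by more than counting noise and were kept as 2 samples. Over 12847 genes with a mean of at least 100 counts, the log2 ratio had an SD of 0.21. Of these genes 34, or 0.265%, were over 2-fold apart, 23 higher in replicate 2 and 11 higher in replicate 1.

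Genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were higher in replicate 2. All 11 list members were higher, with a median log2 ratio of 3.10, against -0.22 to 0.18 for the central 95% of random lists. Most members were scarce in replicate 1, where the list median was 0.42 TPM, against 3.71 TPM in replicate 2. With a pseudocount of 5 counts the median log2 ratio was 2.72. Ttr, the thyroid hormone carrier of that epithelium on chromosome 18 (20665280 to 20674321), had 99 counts in replicate 1 and 9070 in replicate 2, a ratio of 90.0 (95% interval 74.2 to 111). Kl, which encodes the coreceptor klotho, was 3.79-fold higher (3.11 to 4.67), the ion transport gene Clic6 3.24-fold (2.53 to 4.23) and the potassium channel gene Kcnj13 3.19-fold (2.12 to 5.03). F5 (12.4-fold, 7.95 to 21.4) and Tmem72 (7.82-fold, 5.38 to 12.1) were among the 10 largest ratios, though Tmem72 had a log2 ratio of 0.22 in the second transcript table. The thalamus and hippocampus lists were also higher in replicate 2, while the striatum list was lower. The thalamus list had a median log2 ratio of 0.34, with Slc17a6 and Ramp3 among its most abundant members, and its member Prkcd was 2.41-fold higher (2.12 to 2.77). The hippocampus list had a median of 0.55 over 7 members (0.32 in the second transcript table), led in level by Trpc6 (-0.095), Prox1 (0.30) and Fibcd1 (-0.11), and its member Dsp rested on 13 and 50 counts.

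Relative to the bulk of genes, the lists for microglia, complement, antigen presentation and interferon response were lower in replicate 2. Peripheral immune genes were not apart, but only 5 members were used, and random lists spanned -0.31 to 0.31. A median such as the -0.23 of the plaque-associated list would not have been called apart there. All 12 homeostatic microglia genes were lower, with a median log2 ratio of -0.34. Csf1r and Fcrls, among its most abundant members, had log2 ratios of -0.36 and -0.42, and Selplg had -0.48. The plaque-associated list had a median of -0.23, or -0.019 with spike-in totals as size factors, with 22 of 23 members lower, Gpnmb at -0.55 and Lgals3 at 0.69 on 9 and 15 counts. All 22 complement and lysosome genes were lower, with a median of -0.28. Ctss had a log2 ratio of -0.41, Lamp1 of -0.04 and C1qa, a subunit of the complement initiator C1q, of -0.68. Of 12 antigen presentation genes, 11 were lower, with a median of -0.47. B2m, Cd74 and H2-D1 had log2 ratios of -0.3, -0.49 and -0.55, and Psmb9 had -1.01 on 60 and 30 counts. The interferon response list had a median of -0.26, which lay within the central 95% on deposited TPM or with the mean, with Ifitm3 at 0.07, Ifi27l2a at -0.66 and Usp18 on 32 and 16 counts. Reactive astrocyte genes had a median of -0.30 and a mean of -0.18, with Gfap at -0.38, C4b at -0.38 and Serpina3n at -0.52, while Cxcl10 had 0.68 on 14 and 23 counts. All 12 astrocyte genes were lower, with a median of -0.16 (0.049 with spike-in totals) and Sox9 at -0.23. Blood cell genes had a median of -0.58 over 5 members, or -0.34 in the second transcript table, with Alas2 at -1.06. The other 4 members, Hba-a1, Hbb-bs, Hba-a2 and Hbb-bt, share over 50% of their 50-mers with other genes, so the list could not be tested without them. With spike-in totals, medians were nearer to 0 for homeostatic microglia (-0.13), complement and lysosome (-0.065), antigen presentation (-0.26), interferon response (-0.052), reactive astrocytes (-0.091) and blood cells (-0.37). Lists that track RNA quality differed too: relative to the bulk of genes, 12 of 13 mitochondrial mRNAs and 18 of 20 ribosomal protein genes were lower in replicate 2, though both medians were above 0 with spike-in totals, and 10 of 12 nuclear and non-polyadenylated RNAs were higher.

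Neuronal lists differed little. Excitatory neuron, upper layer and synapse medians were 0.02, 0.03 and 0.02 and lay within the central 95%, with Neurod6 at 0.35, Rspo1 at -0.39 and Sv2a at 0.09. All 12 inhibitory neuron genes were higher in replicate 2, with a median of 0.07 (0.12 in the second transcript table) and Pvalb at 0.33, though this list lay within the central 95% on deposited TPM. Deep layer genes had a median of 0.11 with Fezf2 at 0.32, and this list lay within the central 95% on deposited TPM or with the mean. Nuclear and non-polyadenylated RNA had a median of 0.08 and lay within the central 95% with the mean; Malat1 had 0.08, Rn7sk 0.01, Rpph1 -0.10 and Terc 0.94 on 8 and 16 counts. The medians of the remaining lists outside the central 95% were lower relative to the bulk of genes and above 0 with spike-in totals. They were oligodendrocytes (-0.06, with Cldn11 at -0.30), striatum (-0.09), mural cells (-0.17, with Tagln at -0.69) and Alzheimer risk genes (-0.12, with Clu at -0.20, Ptk2b at -0.06, Plcg2 at -0.44 and Mef2c at 0.03). The others were glucocorticoid response (-0.10, with Mt1 at -0.38, Mt2 at -0.26, Plin4 at -0.735 and Sgk1 at 0.02), mitochondrial mRNA (-0.13) and ribosomal proteins (-0.10, with Rpl41 at -0.05, Rplp1 at -0.13 and Rps29 at -0.195). Of the ribosomal proteins Rpl10 was higher, at 0.36, against -0.03 in the second transcript table. Oligodendrocytes and mural cells lay within the central 95% on deposited TPM or with the mean, and Alzheimer risk genes did from 500 counts. On deposited TPM the medians shrank to -0.041 for Alzheimer risk genes, -0.051 for glucocorticoid response, -0.083 for mitochondrial mRNA and -0.054 for ribosomal proteins. Within the central 95% lay oligodendrocyte precursors (-0.07, with Bmp4), endothelial cells (-0.06, with Cdh5), meningeal fibroblasts (0.03, with Igf2, Slc6a13, Dcn and Slc47a1) and peripheral immune cells (-0.02, with Trbc2, Mrc1 and F13a1). So did immediate early genes (0.04, with Homer1, Arc, Egr1 and Egr2), clock genes (0.01, with Tef, Dbp, Nr1d1 and Per2), heat shock (-0.02, with Hspa8, Hsp90aa1, Hsph1 and Hspa1b) and cholesterol synthesis (-0.001, with Hmgcs1 and Srebf2). Some of these were outside it under an alternative: oligodendrocyte precursors, endothelial cells and immediate early genes in the second transcript table, endothelial cells and clock genes with the mean, and heat shock from 500 counts. In all, 21 of 33 lists lay outside the central 95%, 6 higher and 15 lower in replicate 2, against 1.65 by chance for independent genes. With spike-in totals as size factors, the median of all genes moved to 0.21 and the split became 14 higher and 7 lower, so directions are relative to the bulk of genes. mt-Atp6 had a log2 ratio of -0.62, against -0.1 in the second transcript table, and 99.5% of its 50-mers occur in another gene.

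**Figure D2:**
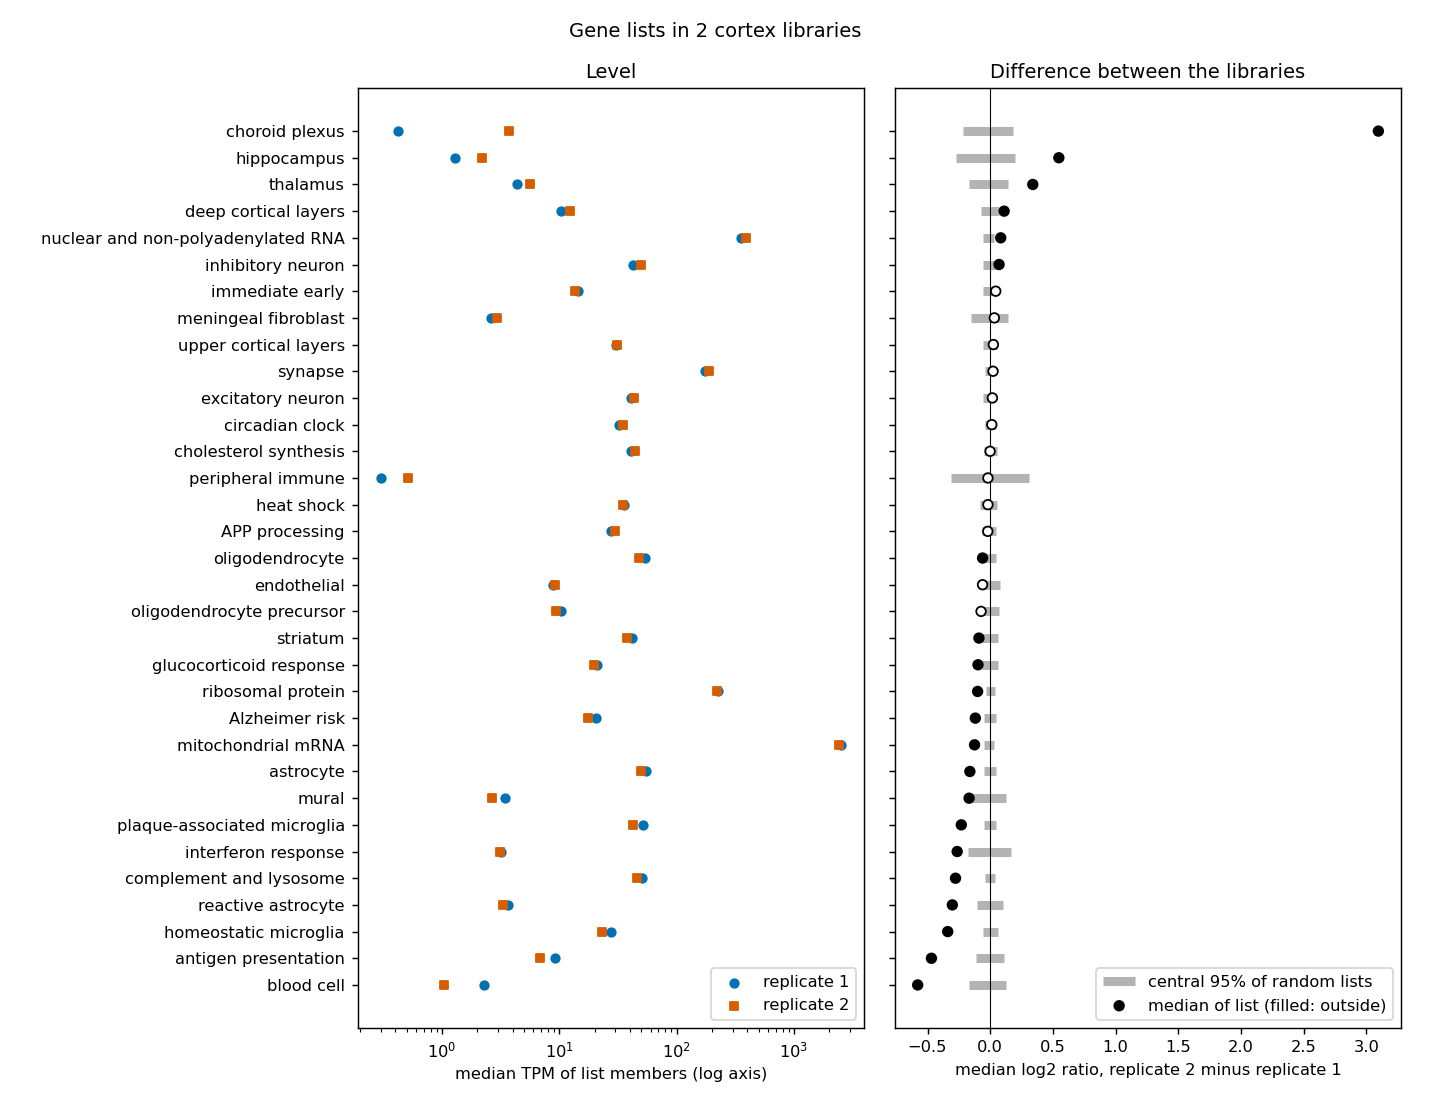
Median TPM of each gene list on a log axis (left; circles replicate 1, squares replicate 2) and median log2 ratio of replicate 2 minus replicate 1 (right; gray bars, central 95% of matched random lists; filled points, outside it). The choroid plexus list lies farthest right at 3.10 and the blood cell list farthest left at -0.58, though in the second transcript table antigen presentation was lowest at -0.46.

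**Figure D3:**
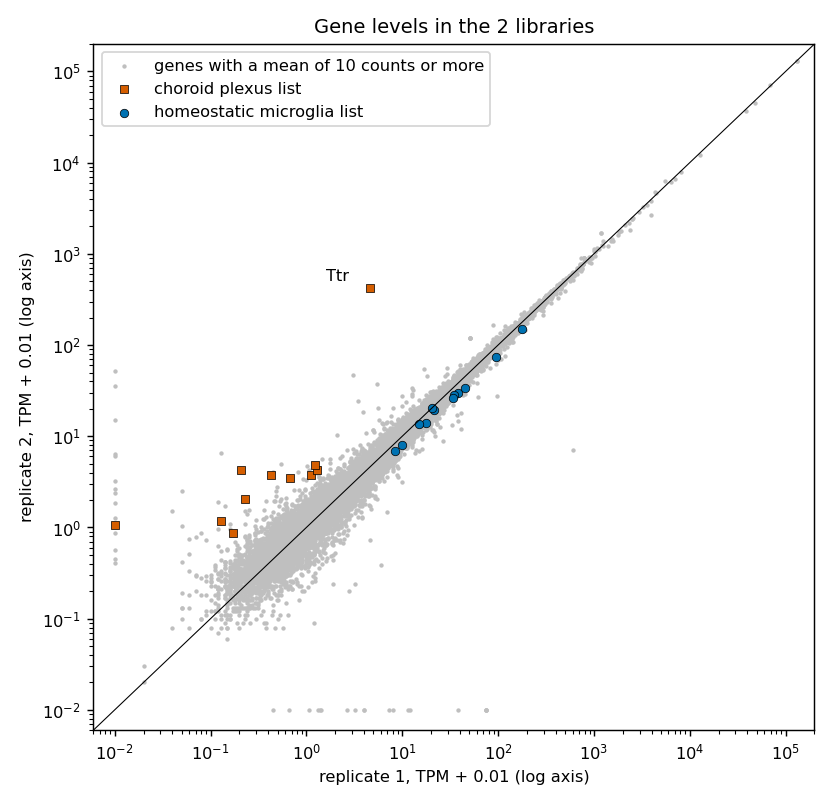
TPM + 0.01 of each gene with a mean of at least 10 counts in replicate 1 (horizontal log axis) and replicate 2 (vertical log axis), with the line of equal values. The 11 choroid plexus genes (squares) lie above the line, Ttr farthest among abundant genes, and the 12 homeostatic microglia genes (circles) lie slightly below it.

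Outside the choroid plexus list, most large ratios belonged to genes with near copies. Of these 30 genes, 24 shared over 50% of their 50-mers with another gene. The pseudogene Gm10359 had 0 counts in replicate 1 and 270 in replicate 2, and the small nuclear RNA gene Gm24497 had 1088 and 13. Gm10163, Gm14288, Gm6565 and Gm45062 were likewise higher in replicate 2. Gm28539, 1700047I17Rik2, Gm14440, Gm21887, Gm6361, Gm12070, Gm10222 and Rpsa-ps10 were higher in replicate 1. In the second transcript table Gm10359, Gm24497, Gm6565, 1700047I17Rik2, Gm6361 and Gm10222 were at 0 TPM in both libraries. Mid1, on the X chromosome, encodes a ubiquitin ligase, and its ratio of replicate 2 over replicate 1 was 0.407 (0.319 to 0.513). The 6 genes left without shared sequence were F5, Tmem72, Prkcd, Mid1, Abca4 and an entry of Nnt, of which Abca4 and Nnt were named after their values were seen. The other Nnt entry moved the opposite way, and Abca4 had a log2 ratio of -0.07 on deposited TPM.

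Most of the genes chosen for isoforms had 1 dominant transcript. App-201 held 89.9% ± 0.478 of App TPM and App-202 4.92% ± 0.217. Clu-201 held 97.0% ± 0.455, with Clu-208 at 0.783% ± 0.28, and Gfap-201 held 94.2% ± 0.0509, with Gfap-202 at 5.56% ± 0.085. In the second transcript table Clu-201 held 79.0%, Gfap-201 90.0% and Gfap-202 9.87%. Apoe-209 held 82.6% ± 0.485 and Apoe-206 10.3% ± 0.321, but Apoe-209 held 50.9% in the second transcript table. Trem2-201 held 81.4% ± 5.51 and Trem2-202 15.2% ± 5.63. Mapt-204 and Mapt-207 held 67.4% ± 3.41 and 14.5% ± 3.66. Bin1-201 held 50.3% ± 1.69 and Bin1-205 20.1% ± 2.98, the latter 8.30% in the second table. Thy1 differed from the rest: Thy1-203, a non-coding transcript of 449 nt, held 51.2% ± 1.23, and the coding Thy1-201 held 47.7% ± 1.12. Both exons of Thy1-203 (chromosome 9, 44047922 to 44047992 and 44048197 to 44048574) lie in the 3 prime UTR in exon 4 of Thy1-201. Reads within those exons can belong to either transcript. The Thy1 shares are therefore an assignment by the quantifier, and reads across the Thy1-203 junction were not examined. Across transcripts, the 2 tables of 1 library had a Spearman rho of 0.676 in replicate 1 and 0.676 in replicate 2, with Pearson r of 0.817 and 0.813.

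**Figure D4:**
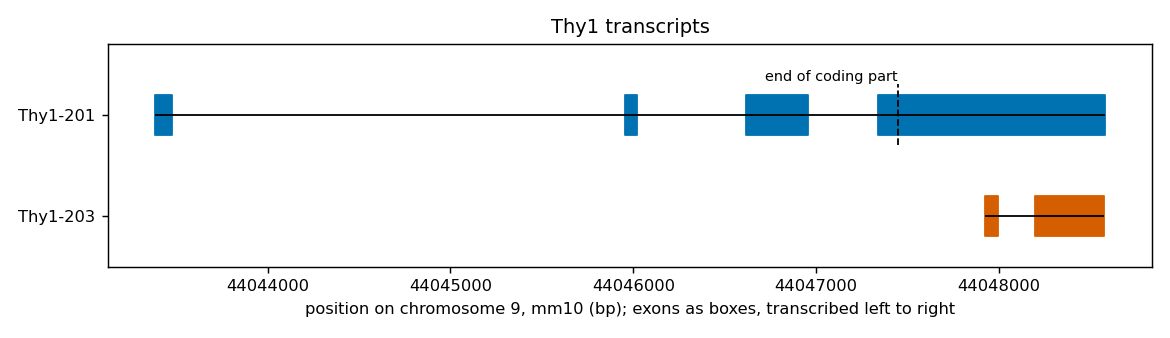
Exons of Thy1-201 and Thy1-203 as boxes along chromosome 9 in mm10 (horizontal axis, bp), with a dashed line at the end of the coding part of Thy1-201. Thy1-203 lies within the last exon of Thy1-201, past the coding part, which ends at 44047448.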

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

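Tests of the Ttr gene alone, of dilution, of a lower share of microglia, of the Thy1 cassette and of Thy1 in the second transcript table were chosen only after the result was seen. Entries outside the comparisons held few counts. PhiX, a sequencing control, had 177 counts in replicate 1 and 168 in replicate 2, and tRNA entries had 5 and 6.87, all above the 3 counts that a 0 allows.

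Choroid plexus genes were higher in replicate 2. The difference was not confined to Ttr, since the other 10 list members had a median log2 ratio of 3.0. With all 11 members higher and a list median of 3.10, this outcome was known before the test and adds no support. A fault of 1 quantifier was excluded, since the list median was 3.02 in the second transcript table. Of 15 further choroid plexus genes, in no other list and written down before their values were looked up, 12 had enough counts, and all 12 were higher with a median of 0.59, against -0.14 to 0.12 for random lists; Enpp2, the most abundant, was at 88.3 TPM in replicate 1 and 166 in replicate 2. Choroid plexus tissue in the replicate 2 sample is therefore a candidate explanation: in replicate 1, 4 of 11 list members and 8 of the 15 further genes already reached 1 TPM, and no biological explanation was tested, as there is 1 group.

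Microglial lists were lower in replicate 2. Dilution by tissue without neurons would lower neurons alike, but the excitatory neuron median lay 0.36 above the homeostatic microglia median. This comparison cannot decide on dilution by tissue that holds neurons, and the hippocampus (0.55) and thalamus (0.34) lists were higher in replicate 2. A fault of 1 quantifier was excluded by a homeostatic median of -0.3 in the second transcript table. A lower share of microglia in replicate 2 stays open as a candidate explanation: 10 microglial members of the plaque-associated list lay 0.06 above the homeostatic median, and all its members 0.11, but C1qa had a log2 ratio of -0.68 and Siglech of -0.12, so it may not be the whole cause. Blood cell, astrocyte, antigen presentation, mitochondrial mRNA and ribosomal protein lists were lower as well and nuclear RNA was higher (0.08); neither RNA quality nor a biological explanation was tested for this pattern.

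A short Thy1 transcript was at the level of the coding one. A general rise of coverage towards 3 prime ends was argued against, since 2 of 519 other genes with a short transcript in a 3 prime UTR, or 0.385%, had as large a share. A fault of 1 quantifier was argued against by a share of 49.0% in the second table. Both tables divide reads of the same libraries over the same annotation, so this cannot show that Thy1-203 is a separate transcript. Reads of the Thy1 cassette of the transgenes may add to this part, but the location predicted for that, the 5 prime part of the gene, was wrong: 100% of Thy1-203 lies in the last exon of Thy1-201. Whether these samples carry the transgenes, and whether the transgenes keep this exon, is not given in the sources used here. Without cortex labelled non-transgenic, reads of the cassette cannot be told apart from native transcription.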

How the results depend on the processing

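The 2 alternatives that leave out shared sequence were chosen after seeing the data. The common biological coefficient of variation of 0.0629 was 0.0639 with library totals, 0.0487 from 500 counts, 0.0546 for nuclear protein-coding genes and 0.119 by DESeq2 dispersion. The 34 genes over 2-fold apart became 22 in the second transcript table, 6087 with no count filter and 3 from 500 counts. They became 20 for nuclear protein-coding genes, 111 at a ratio over 1.5 and 6 without choroid plexus list members and shared-sequence genes. Whether these 6 relate to choroid plexus was not tested. With no filter or a lower threshold more genes pass by construction, and with fewer genes tested fewer do. With spike-in totals 28 were higher and 8 lower, against 23 and 11. The 21 lists apart became 13 of 22 tested from 500 counts, and 16 to 25 under the other alternatives, 20 without shared sequence. The 21 lists at 10 TPM or more were 19 to 25, and 21 to 22 with 1 replicate left out. Levels of single genes also depended on the table, as given above for mt-Atp6, mt-Co3, mt-Atp8, Snurf and App. Pearson r between the libraries was 0.968 with a pseudocount of 0.1, 0.979 from 1 TPM and 0.992 in the second table. For agreement of the 2 transcript tables, rho was 0.604 from 1 TPM and r was 0.713 with a pseudocount of 0.1, against 0.676 and 0.815; rho was 0.675 to 0.676 with 1 replicate left out. Of the lists apart, spike-in totals changed the sign of the median for astrocytes (0.049), oligodendrocytes (0.15), mural cells (0.043), striatum (0.12), Alzheimer risk (0.093), glucocorticoid response (0.11), mitochondrial mRNA (0.087) and ribosomal proteins (0.11), because all genes moved by 0.21. Deposited TPM turned oligodendrocytes (0.017) and Abca4 (-0.070), and of lists within the central 95% also oligodendrocyte precursors (0.0245), APP processing (0.0205), heat shock (0.0212), cholesterol synthesis (0.0564) and meningeal fibroblasts (-0.0222). Other medians near 0 changed sign under other alternatives too; the cause was not tested for these or for the other values above. Of the 34 genes, 11 had under 3 counts in the second table and no ratio there. Comparisons between the libraries have no value with 1 left out. No paired analysis was possible because there was 1 group. Depth limits the blood cell, hippocampus and peripheral immune lists, whose members often had few counts, and in replicate 1 also the choroid plexus list.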
